A study of Mus musculus with 6 samples.

How the data were processed

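Total RNA from the mesenteric arteries of 6 mice was labelled with biotin and hybridised to Affymetrix arrays, 1 array per mouse. Per the labels, the control group held 3 mice with loxP-flanked beta1 integrin alleles and no recombinase, and the knockout group held 3 mice with the same alleles and an SM22alpha-driven Cre recombinase. The labels' protocols state that adipose and lymph tissue were removed from the vessels before extraction. Each array carries its own animal number, and the labels state nothing more on litters or days.

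The deposited values are 1 linear intensity per probe set, for 45037 probe sets on each array. The method by which the authors summarised probes and scaled arrays is not given in the sources used here. Between 589 and 680 values per array are exactly 1, and the highest values lie between 16161 and 18776. The table carries no detection calls, and the number of arrays, 3 per group, limits the precision.

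Probe sets were named through the platform annotation of 2016, in which 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Only those with 1 symbol entered the tests by gene. The other 10092 were tested on their own, after the same filter, without naming them. Gene identifiers were looked up in a reference table of GRCm38.p6, which held those of 34741 probe sets and changed 0 symbols, and which also gave the order of genes along chromosomes. No coordinates are printed, since no genome build is named for the array.

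Intensities were transformed to log2(intensity + 1) and quantile normalized between arrays. Probe sets whose mean over the 6 arrays lay under the median of all such means, a log2 value of 6.50, were left out, which left 17473 probe sets. Each gene was represented by its probe set with the highest mean, giving 10654 genes. All log2 differences are knockout minus control on the log2(intensity + 1) scale, which understates changes of genes with low signal. The 2 groups were compared with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes, 2-sided, and Benjamini-Hochberg adjustment over the 10654 genes. A gene past the threshold has an adjusted p under 0.05. Single values of the targeted gene were also compared by a 2-sided exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1.

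Before the data were examined, 44 gene lists were fixed from general knowledge of vessel wall, integrin and matrix biology, of other cell types of the mesentery and of common nuisance factors. Of 597 listed genes, 550 are named on the array and 438 passed the filter; the other listed genes are not analysed here. The 32 lists with at least 5 genes tested were compared with all other genes by camera (preset correlation of 0.01), with Benjamini-Hochberg adjustment over the 32 lists. Beside it stand camera with a correlation estimated from the arrays and fry, which tests whether a list's genes move on balance one way. The mixed form of fry tests for change in either direction. It does not compare a list with other genes, and its p is given unadjusted. Members past an adjusted p of 0.05 were counted over all genes and adjusted over the list alone.

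The genes named in the text were set by a rule, also fixed beforehand. It names Itgb1 and Tagln, the 12 genes with the largest positive and the 12 with the largest negative change among those past the threshold with no overlap between groups, up to 4 members per list with the smallest p, and Xist with the Y-linked genes. Predicted transcripts were skipped, of which 6 passed the threshold. Genes named outside this rule are marked as chosen after their values were seen.

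The procedure was tested on 20 simulated data sets of 10654 genes with 200 changed genes and 3 arrays against 3. It recovered 52.0% of genes changed by 1 on the log2 scale and 91.6% of those changed by 2, with 4.45% false calls. Lists of 20 genes shifted by 0.5 were called in 100% of simulations, and unchanged lists in 5%. In the simulations a list was called by its unadjusted camera p, whereas the reported list calls are adjusted over all lists tested. The simulated list rates thus belong to a looser criterion than the reported calls. The simulated genes were drawn independently of each other. Their spread came from the variance prior that limma itself fitted, with normal errors and equal variance on all arrays. A share of false calls near the threshold is thus built in, and the recovery holds only under that model. In the data the correlations estimated within lists reach 0.874, so these rates do not carry over to correlated genes.

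Alternatives fixed beforehand were no filter, a filter at the 70th percentile, the mean of all probe sets of a gene, a test by probe set, median centring, a pseudocount of 16, a trended robust prior, array weights, the white adipocyte list as a covariate, other thresholds, other list tests, and leaving out each array in turn. Alternatives added after seeing the data were no normalization between arrays, the macrophage list as a covariate, 2 against 2 arrays and 3 against 1. The fit of 2 against 2 left out control 30 and knockout 86. The fit of 3 against 1 left out knockouts 73 and 86, so knockout 72 alone stood for its group. Neither of these fits includes knockout 86, the array with high Xist. The macrophage list means of the groups do not overlap (7.77 to 8.78 in control and 9.21 to 10.92 in knockout arrays). All fits with that covariate therefore rest on differences within groups and cannot separate macrophage content from group. The letter in the array titles is F for knockout 86 and M for the other 5 arrays. It was not used as a covariate, since the labels do not state its meaning and it would remove that array. Plots were drawn with matplotlib 3.10.9.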

Results

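Gene expression was measured in mesenteric arteries, the small arteries that supply the gut, from 3 control mice (animal numbers 30, 74 and 75) and 3 knockout mice (72, 73 and 86). The knockout mice carried a Cre recombinase under the promoter of SM22alpha (Tagln), a gene of smooth muscle, in addition to floxed Itgb1, which encodes beta1 integrin. All 6 mice had received 1 mg of tamoxifen per day for 14 days from 5 weeks of age and were 7 weeks old. The comparison asks how the arterial transcriptome differs once beta1 integrin has been deleted in smooth muscle.

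The median intensity per array lay between 62.8 and 72.6. Pearson correlations across genes, which are not independent replicates, were 0.925 to 0.959 among control arrays, 0.945 to 0.969 among knockout arrays and 0.877 to 0.940 between groups. The first principal component held 47.6% of the variance and separated the groups, and the second held 26.1%. Xist had a log2 value of 11.83 in knockout 86 and of 5.29 to 6.09 in the other 5 arrays. The Y-linked genes ran the opposite way, with Eif2s3y at 2.04 in knockout 86 and 8.63 to 9.07 elsewhere. Uty stood at 2.17 against 7.64 to 8.08, and Kdm5d at 3.46 against 7.53 to 7.99. By these genes knockout 86 came from a female and the other 5 arrays from males, so sex is partly confounded with group.

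The targeted gene was lower in all 3 knockout arrays than in any control array. Itgb1, in its probe set with the highest signal, had a mean log2 value of 11.35 ± 0.40 (SD, n = 3) in control and 10.61 ± 0.13 (SD, n = 3) in knockout arteries. The difference was -0.73 (SE 0.22), which leaves 60.1% of the control level (95% confidence interval 42.2 to 85.6). It did not pass the threshold over all genes (limma adjusted p = 0.127, unadjusted p = 0.0115). Whole arteries were measured, so this level does not give the extent of deletion in smooth muscle cells. The other 2 Itgb1 probe sets above the filter stood at 58.0% and 61.6% of control. For each of the 3 the exact permutation p was 0.1, the smallest possible. The probe set at 58.0% carries the suffix x, which marks probes shared with similar sequences. The 3 Itgb1 probe sets below the filter stood at 56.9%, 57.9% and 103% of control (exact permutation p = 0.2, 0.2 and 0.9). Where these probe sets lie relative to the floxed exon is not given in the sources used here. Tagln differed by -0.33 (SE 0.14, adjusted p = 0.231).

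**Figure D1:**
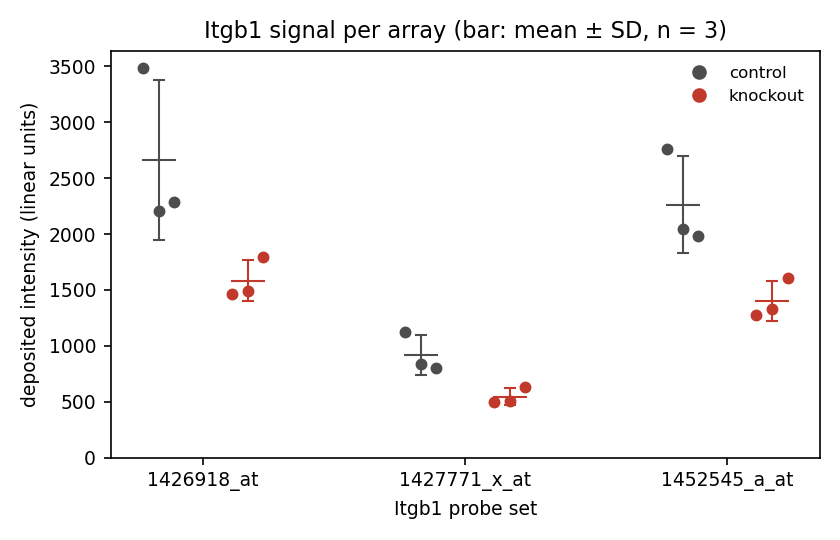
Deposited intensity (linear units, vertical axis) of the 3 Itgb1 probe sets above the filter (horizontal axis), with 1 point per array and bars for the mean and SD of 3 control and 3 knockout arrays. In every probe set each knockout array lies below each control array; for the probe set with the highest signal the knockout arrays lie between 1468 and 1795 and the control arrays between 2203 and 3487.

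Of the cell cycle genes tested, 12 of 14 rose in knockout arteries, as did 9 of 22 interstitial matrix genes and 6 of 16 genes of the synthetic smooth muscle state, while these lists did not pass camera with an estimated correlation (adjusted p = 0.133, 0.159 and 0.159). Of 10654 genes tested, 258 passed the threshold, 188 higher and 70 lower in the knockout, and 181 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 2279 genes. None of the 258 genes had overlapping groups; among all genes tested, 28.1% had no overlap, where chance gives 10%. The count fell to 116 without control 30, 62 without control 75, 45 without knockout 72, 100 without knockout 73 and 69 without knockout 86, and was 240 without control 74.

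The largest increases were those of Ube2c, a ubiquitin-conjugating enzyme of mitosis, by 4.80 on the log2 scale (SE 0.40, 27.8-fold, adjusted p = 0.00303), and of the kinetochore gene Nuf2, by 4.59 (SE 0.29, 24.1-fold, adjusted p = 0.00144). Cdk1 rose by 4.44, Cep55 by 4.27, Top2a by 4.26, Spc25 by 4.17, Ccna2 by 4.04, Cdca8 by 3.95 and Pbk by 3.92, and Mki67 rose 16.01-fold. Outside this proliferative set, the mineralised matrix protein gene Dmp1 rose by 4.36 (SE 0.28, adjusted p = 0.00144) and the osteoprotegerin gene Tnfrsf11b by 3.87 (SE 0.43, adjusted p = 0.0107). In all 12 genes the control mean lay below the filter level of 6.50, so the size of these folds depends on the pseudocount. Of the 12, Tnfrsf11b alone lost its call in a fit of 5 arrays (adjusted p = 0.0504 without control 75).

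The largest decreases were those of the transmembrane collagen Col13a1, which fell by 3.09 on the log2 scale (SE 0.28, 8.53-fold, adjusted p = 0.00417), and of Gdpd3, which fell by 3.08 (SE 0.49, adjusted p = 0.0324). The synaptic vesicle gene Sv2b fell by 2.70, while its other probe set above the filter stood at -1.07 (unadjusted p = 0.00728). Tesc fell by 2.08, the metalloproteinase inhibitor Timp4 fell by 1.75 and Smim5 fell by 1.61. The mineralocorticoid receptor gene Nr3c2 fell by 1.59 (SE 0.16, adjusted p = 0.0057), Sox6os fell by 1.59, Xkr4 fell by 1.56, the potassium channel gene Kcna5 fell by 1.53, the cartilage cytokine Cytl1 fell by 1.49 and Gstm1 fell by 1.46. The Gstm1 probe set carries the suffix x, which marks probes shared with similar sequences, so its value is uncertain among close paralogs; its 2 probe sets without this suffix stood at -1.47 and -1.14 (unadjusted p = 0.00211 and 0.00139). Col13a1 and Nr3c2 remained past the threshold without any 1 array. The other 10 lost their calls without control 30, all except Tesc without knockout 72 and all except Xkr4 without control 75, with highest adjusted p-values between 0.0763 (Sox6os) and 0.16 (Gstm1).

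Most cell cycle genes rose. Of 14 genes tested, 12 rose over all genes and 14 adjusted over the list alone, and in all 14 the groups did not overlap. The count of 12 was 15 with no filter, where all 20 members on the array were tested, 14 with array weights and 13 with a pseudocount of 16. It was 10 with the macrophage covariate and 8 with 2 against 2 arrays. With the 70th percentile filter it was 7, but only 145 of the 258 genes past the threshold were still tested there. Mki67, Top2a, Cdk1 and Birc5 have control means below the filter level and passed the filter through their knockout signal. Mki67 rose 16.01-fold (SE 0.20 on the log2 scale, adjusted p = 0.00103), Top2a 19.2-fold (SE 0.21, adjusted p = 0.00103; its other probe set above the filter stood at 0.40 on the log2 scale, unadjusted p = 0.118), Cdk1 21.6-fold (SE 0.26, adjusted p = 0.00132) and Birc5 9.47-fold (SE 0.22, adjusted p = 0.00176). The list mean was higher by 2.38 (camera adjusted p = 4.95e-22, adjusted p = 0.133 with an estimated correlation, fry adjusted p = 0.00101). It stood at 7.02 to 7.19 in the control arrays and at 9.28 to 9.67 in the knockout arrays. The 2 members not past the threshold, named after their values were seen, were the replication licensing genes Mcm2 (0.89, adjusted p = 0.0794) and Mcm4 (0.52, adjusted p = 0.143). The p53 targets, which include the cell cycle inhibitor Cdkn1a at 1.21 (adjusted p = 0.113), had a mean of 0.13 and 0 of 8 genes past the threshold (adjusted p = 0.384, adjusted p = 0.688 with an estimated correlation).

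**Figure D2:**
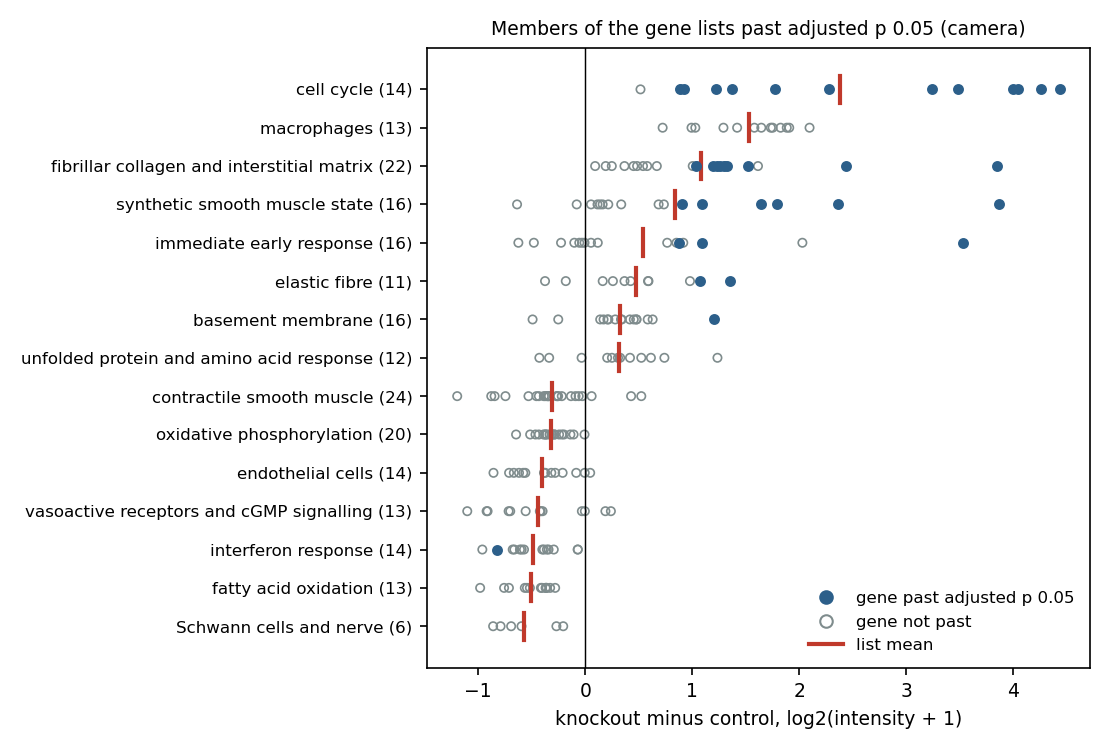
Log2 difference, knockout minus control (horizontal axis), of each tested gene in the 15 lists past an adjusted p of 0.05 by camera (vertical axis, number of genes tested in brackets), with filled points for genes past the threshold, open points for the others and a bar for the list mean. The cell cycle list has a mean of 2.38 and the fibrillar collagen and interstitial matrix list a mean of 1.08.

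All 22 collagen and interstitial matrix genes tested were higher in the knockout, 9 passed the threshold over all genes and 17 adjusted over the list alone. Timp1 rose by 3.85 (SE 0.37, 14.4-fold, adjusted p = 0.00565), Col5a2 by 1.52 (SE 0.15, adjusted p = 0.00565), Fn1, the gene of the integrin ligand fibronectin, by 1.19 (SE 0.12, adjusted p = 0.00628), and Col5a1 by 1.26 (SE 0.15, adjusted p = 0.0121). The list mean was higher by 1.08 (camera adjusted p = 4.33e-16, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.00512). Of the 9 calls, 4 were left without control 75, 2 without knockout 72, 4 without knockout 73 and 3 without knockout 86. The count of matrix genes was 4 with no filter, 14 with array weights, 2 with the macrophage covariate, where the list mean was 1.20, 1 with 2 against 2 arrays and 0 with 3 against 1. Fn1 lost its call without knockout 72 (adjusted p = 0.0546), and Col5a1 lost it without knockout 72 or knockout 86 (highest adjusted p 0.0667). Adventitial fibroblast genes, the other source of such transcripts on the lists, had a mean of 0.25 (adjusted p = 0.1, adjusted p = 0.725 with an estimated correlation), and 1 of 11, Mfap5, rose. This list mean ranged from 0.06 to 0.35 with 1 array left out, and passed camera without control 74 (0.35, adjusted p = 0.0349), control 75 (0.35, adjusted p = 0.0328) or knockout 86 (0.31, adjusted p = 0.0411), as well as with the adipocyte covariate (0.40, adjusted p = 0.00346, 3 genes higher past the threshold). The macrophage covariate turned it to -0.05.

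Elastic fibre genes had a mean of 0.48 (camera adjusted p = 0.00185, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.00573). Of 11 tested, 2 rose over all genes and 3 adjusted over the list alone. These 2, Mfap5 (1.08, adjusted p = 0.0224) and Mfap2 (1.35, adjusted p = 0.0487), encode microfibril proteins, while the crosslinking enzyme Lox stood at 0.98 (adjusted p = 0.133) and Loxl1 at 0.59 (adjusted p = 0.149). In the fits of 5 arrays, Mfap5 was past the threshold only without control 74 and Mfap2 in none of 6. Basement membrane genes had a mean of 0.32 (camera adjusted p = 0.00062, adjusted p = 0.369 with an estimated correlation, fry adjusted p = 0.012). Of 16, 14 were higher, 1 rose over all genes and 2 adjusted over the list alone. Col15a1 rose by 1.20 (SE 0.15, adjusted p = 0.0159), with highest adjusted p 0.0802 among the fits without control 75, knockout 72 or knockout 86, in which its call was lost, and Lamc1 stood at 0.63 (adjusted p = 0.0925).

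Some genes listed for the synthetic smooth muscle state rose. RNA came from whole arteries, so the cells that carry these transcripts are not known. Egr1, also counted in the immediate early response, is among them. Of 16 synthetic state genes, 6 rose over all genes. Adjusted over the list alone, 8 rose and 1 fell, which is Mmp9 at -0.64, named after its values were seen. Among the 6 were S100a4 at 1.64 (SE 0.13, adjusted p = 0.00296), Thbs1 at 2.37 (SE 0.27, adjusted p = 0.0121) and Tpm4 at 0.90 (SE 0.12, adjusted p = 0.0203). The list mean was higher by 0.84 (camera adjusted p = 7.48e-06, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.00512). Its count of 6 fell to 2 without control 75 or knockout 72 and to 3 without knockout 73 or knockout 86. It was 4 with no filter or with 2 against 2 arrays, 3 with the macrophage covariate and 0 with 3 against 1. In the fits of 5 arrays, Thbs1 lost its call without knockout 72 (adjusted p = 0.0612) and Tpm4 kept it only without control 74 (highest adjusted p 0.0799).

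Of 24 contractile genes, 0 passed the limma threshold over all genes and 1 adjusted over the list alone. In other settings 1 fell, with median centring or the adipocyte covariate, or 2, with array weights or without control 74. The list mean was -0.31, with 21 of 24 genes lower (camera adjusted p = 0.00448, adjusted p = 0.725 with an estimated correlation, fry adjusted p = 0.37). The list was not past the threshold without control 30 (mean -0.15, adjusted p = 0.248) or without knockout 73 (mean -0.23, adjusted p = 0.0775), and its mean was -0.53 without control 74. With the macrophage covariate, whose values do not overlap between groups, the call was lost and the direction reversed (0.12, adjusted p = 0.392). Lmod1 stood at -1.20 (adjusted p = 0.0567), Ppp1r14a at -0.88 (adjusted p = 0.117), Synpo2 at -0.75 (adjusted p = 0.127) and Myh11 at -0.46 (adjusted p = 0.133). Acta2, chosen after its values were seen, differed by -0.03 (SE 0.12, adjusted p = 0.917) and by 0.01 with no normalization between arrays. Pericyte genes, which overlap with mural smooth muscle, had a mean of -0.21 (adjusted p = 0.581, adjusted p = 0.885 with an estimated correlation; Notch3 at -0.88, adjusted p = 0.107).

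No integrin gene on the lists passed the threshold, except that with array weights 1 alpha subunit rose and 1 beta subunit other than beta1 fell, and Itgb1 itself passed with array weights or the adipocyte covariate. The alpha subunits that pair with beta1 had a mean of 0.15 over 10 genes (adjusted p = 0.311, adjusted p = 0.776 with an estimated correlation). It was 0.34 (adjusted p = 0.0195) without control 30 and 0.56 (adjusted p = 0.00609) with the macrophage covariate. Itga5, the fibronectin receptor subunit, stood at 0.75 (adjusted p = 0.0688) and Itgav at 0.44 (adjusted p = 0.179). Other Itga5 probe sets above the filter stood at 1.68 and 1.48 (unadjusted p = 0.00438 and 0.00856). The other beta subunits had a mean of 0.30 over 5 genes (adjusted p = 0.384, adjusted p = 0.688 with an estimated correlation), with Itgb5 at 0.47, Itgb4 at -1.01 and the leukocyte subunit Itgb2 at 2.12 (adjusted p = 0.127, 0.128 and 0.157). Focal adhesion genes had a mean of -0.02, a median of 0.0025 and a camera test pointing up (adjusted p = 0.91, adjusted p = 0.955 with an estimated correlation), with 13 genes higher and 12 lower, and their mean was 0.0077 with no normalization between arrays. Among them were Tns3 at 0.51 (adjusted p = 0.0721), Lims2 at -0.80 (adjusted p = 0.0784), Zyx at -0.48 (adjusted p = 0.109) and Tns1 at -0.41 (adjusted p = 0.131). YAP targets likewise split 7 to 7, with a mean of -0.02, a median of 0.02, a test pointing up (adjusted p = 0.921, adjusted p = 0.955 with an estimated correlation) and a mean of 0.03 with no normalization, with Ankrd1 at 1.34 (adjusted p = 0.102) and Ptpn14 at -0.59 (adjusted p = 0.0784).

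Single genes of the TGF-beta and BMP list rose, but not the list as a whole. Ltbp2, named for the latent TGF-beta binding protein family, rose by 3.08 (SE 0.26, 8.44-fold, adjusted p = 0.00314). The ligand Tgfb1 rose by 1.23 (SE 0.16, adjusted p = 0.0183), while its other probe set above the filter stood at 0.22 (unadjusted p = 0.247). The receptor Tgfbr1 rose by 1.02 (SE 0.18, adjusted p = 0.0413). Ltbp2 was past the threshold in all 6 fits of 5 arrays, Tgfb1 only without control 74 and Tgfbr1 in none (highest adjusted p 0.0815 and 0.141). The list of 20 genes had a mean of 0.20, and did not pass camera (adjusted p = 0.374, adjusted p = 0.68 with an estimated correlation). Smad6 stood at -0.61 (adjusted p = 0.0557). Adjusted over the list alone, 3 rose and 5 fell.

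In the immediate early response, 3 of 16 genes rose over all genes and 6 adjusted over the list alone. Egr2 rose by 3.53 (SE 0.28, 11.6-fold, adjusted p = 0.00296), Ier2 by 0.87 (SE 0.13, adjusted p = 0.0297) and Egr1 by 1.09 (SE 0.18, adjusted p = 0.0335), while Egr3 stood at 2.03 (adjusted p = 0.0748). The list mean of 0.54 passed camera (adjusted p = 0.00448, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.227), but not with the adipocyte covariate (0.33, adjusted p = 0.191), and the list median was 0.09. With 1 array left out the mean lay between 0.37, without control 75, and 0.83, without control 30. The list stood at 10.26 in control 30, above knockouts 72 (10.16) and 73 (10.20), and at 9.47 and 9.35 in the other controls. The count was 1 without control 75, knockout 72 or knockout 86. Egr2 was past the threshold in all 6 fits of 5 arrays, Egr1 only without control 30 or control 74 and Ier2 only without knockout 73 (highest adjusted p 0.139 and 0.131).

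Channel genes moved in both directions. Trpc6 rose by 2.17 (SE 0.33, adjusted p = 0.0291) and Kcna5 fell, out of 17 ion channel and calcium handling genes with a mean of -0.27 (adjusted p = 0.133, adjusted p = 0.76 with an estimated correlation). The list passed with the 70th percentile filter (-0.45, adjusted p = 0.0135), the adipocyte covariate (-0.42, adjusted p = 0.0111), array weights (-0.38, adjusted p = 0.0229), without control 74 (-0.51, adjusted p = 0.00706) and without knockout 86 (-0.34, adjusted p = 0.0249). Its mean was -0.13 without control 30 and 0.16 with the macrophage covariate. Of the calls of Trpc6 and Kcna5, 1 was left without control 30 and 0 without control 75, knockout 72, knockout 73 or knockout 86. Vasoactive receptor and cGMP signalling genes had a mean of -0.44 (camera adjusted p = 0.0158, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.235). None of 13 passed the threshold over all genes by limma and 2 fell adjusted over the list alone, with Rgs2 at -1.10 (adjusted p = 0.0833) and Ednrb at -0.91 (adjusted p = 0.0958). Without control 30 that list mean was -0.31 (adjusted p = 0.196), and it was -0.41 (adjusted p = 0.0557) with the mean of all probe sets of a gene and -0.22 (adjusted p = 0.613) with the macrophage covariate.

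Macrophage genes were higher in the knockout as a list by camera, with a mean of 1.53 (adjusted p = 3.25e-07), but not with an estimated correlation (adjusted p = 0.662) or by fry (adjusted p = 0.212). All 13 were higher, 0 passed the limma threshold over all genes and 8 rose adjusted over the list alone. Over all genes 4 rose with array weights and 2 with the adipocyte covariate. Mrc1 stood at 1.42 (SE 0.31, adjusted p = 0.0668), C1qa at 1.29 (adjusted p = 0.0773), Fcgr3 at 2.10 (adjusted p = 0.108) and C1qb at 1.75 (adjusted p = 0.123). The list mean was 7.77, 8.78 and 8.50 in controls 30, 74 and 75, and 9.51, 10.92 and 9.21 in knockouts 72, 73 and 86, and without knockout 73 the difference was 1.01. Inflammatory chemokine and adhesion molecule genes had a mean of 0.26 (adjusted p = 0.133, adjusted p = 0.68 with an estimated correlation), with Cxcl1 at 0.86 (adjusted p = 0.105), over the 10 of 18 members above the filter. Over all 18, with no filter, the mean was 0.60 (adjusted p = 0.0012), and with the adipocyte covariate the 10 genes had 0.48 (adjusted p = 0.0118). With 1 array left out the mean lay between 0.03, without control 30, and 0.47, without knockout 86 (adjusted p = 0.0389), and with the macrophage covariate it was -0.23.

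**Figure D3:**
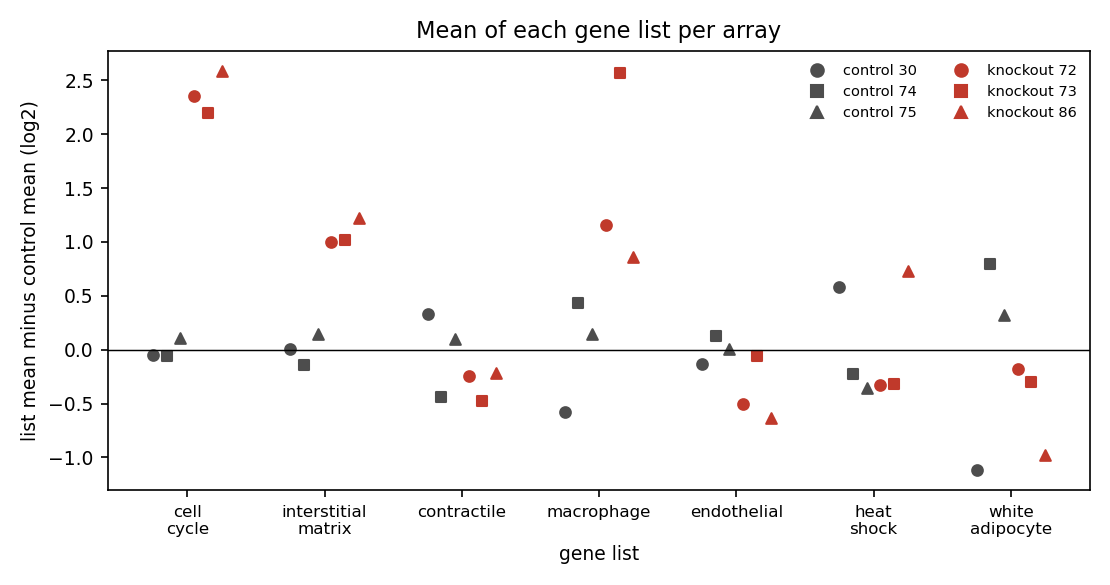
Mean log2 value of 7 gene lists on each array, minus the mean of the 3 control arrays (vertical axis, log2), by list (horizontal axis), with 1 symbol per array. Cell cycle means in the knockout arrays (9.28 to 9.67) lie above all control arrays (7.02 to 7.19), and knockout 73 has the highest macrophage mean, 10.92.

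Endothelial and Schwann cell genes were lower as lists. Endothelial genes had a mean of -0.40, with 13 of 14 lower, 0 past the limma threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.227). Tek stood at -0.62 (adjusted p = 0.091), Nos3 at -0.58 (adjusted p = 0.116) and Pecam1 at -0.86 (adjusted p = 0.123). The 6 Schwann cell and nerve genes had a mean of -0.57, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.136), with S100b at -0.60 (adjusted p = 0.0747) and Cdh19 at -0.79 (adjusted p = 0.0982). White adipocyte genes had a mean of -0.49 (adjusted p = 0.198, adjusted p = 0.776 with an estimated correlation) and ranged from 10.08 in control 30 to 11.99 in control 74, with -1.04 (adjusted p = 0.000105) without control 30 and -1.48 (adjusted p = 0.00342) with the macrophage covariate. Lymphatic endothelial genes had a mean of -0.0017 (adjusted p = 0.834, adjusted p = 0.955 with an estimated correlation) and of 0.03 with no normalization between arrays.

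Interferon response genes were lower, with all 14 below 0 and a mean of -0.49 (camera adjusted p = 0.00201, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.235). The mean was -0.29 without knockout 86 and -0.69 without knockout 73, both past the threshold, and larger still with the macrophage covariate (adjusted p = 2.62e-06). Ifit1 fell by 0.83 on the log2 scale (SE 0.14, adjusted p = 0.0335), the 1 call over all genes, against 2 adjusted over the list alone, and Ifit3 stood at -0.96 (adjusted p = 0.0617). The Ifit1 call was lost without control 30, control 75, knockout 72, knockout 73 or knockout 86 (highest adjusted p 0.139).

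Genes of energy metabolism were lower as lists, with 0 genes past the limma threshold. All 20 oxidative phosphorylation genes were lower, with a mean of -0.32 (camera adjusted p = 0.00206, adjusted p = 0.703 with an estimated correlation, fry adjusted p = 0.305) and Sdha at -0.65 (adjusted p = 0.117). All 13 fatty acid oxidation genes were lower, with a mean of -0.51 (camera adjusted p = 0.00448, adjusted p = 0.695 with an estimated correlation, fry adjusted p = 0.323), Acaa2 at -0.71 (adjusted p = 0.145) and Hadh at -0.76 (adjusted p = 0.147). Adjusted over the list alone, 0 passed in either. Neither list passed without control 74, which has the highest adipocyte mean (-0.12, adjusted p = 0.184, and -0.19, adjusted p = 0.185). With the adipocyte covariate both passed, at -0.19 (adjusted p = 0.0205) and -0.28 (adjusted p = 0.023), and with array weights oxidative phosphorylation did not (-0.14, adjusted p = 0.163).

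The unfolded protein and amino acid response had a mean of 0.32 (camera adjusted p = 0.0104, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.226), with 0 of 12 past the limma threshold and 2 adjusted over the list alone, Pdia4 at 0.74 (adjusted p = 0.0558) and Sdf2l1 at 1.24 (adjusted p = 0.0639). Without knockout 86 its mean was 0.19 (adjusted p = 0.059), and with array weights 0.22 (adjusted p = 0.0779). Hypoxia genes had a mean of -0.39 (adjusted p = 0.325, adjusted p = 0.775 with an estimated correlation), which was -0.60 (adjusted p = 0.0248) without control 30, and circadian genes one of -0.51 (adjusted p = 0.31, adjusted p = 0.695 with an estimated correlation). Heat shock genes had a mean of 0.03, a median of -0.0072, a test pointing up (adjusted p = 0.834, adjusted p = 0.955 with an estimated correlation) and a mean of -0.04 under median centring and of 0.85 (adjusted p = 0.0132) with the macrophage covariate. The list stood at 11.84 in control 30, 11.99 in knockout 86 and 10.90 to 11.03 in the other 4 arrays. Cholesterol synthesis genes had a mean of -0.10 with a test pointing up (adjusted p = 0.91, adjusted p = 0.955 with an estimated correlation). Genes known to vary between inbred strains had a mean of -0.14 (adjusted p = 0.581, adjusted p = 0.729 with an estimated correlation). In these 5 lists, 0 genes passed the limma threshold.

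In all, 15 of 32 lists passed camera, 8 higher and 7 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.133, while 5 passed fry. In 7 of the 15, the contractile, immediate early, interferon, vasoactive, oxidative phosphorylation, fatty acid oxidation and endothelial lists, the means of the control and knockout arrays overlapped. A further 12 lists had fewer than 5 genes above the filter and no list test there. With no filter 10 of them could be tested and 0 passed, the lowest adjusted p being 0.0713 for pancreatic acinar cells (-0.67), followed by 0.0803 for both brown adipocytes (-0.84) and lymphocytes (0.50). Of cartilage and bone genes, 1 of 4, Cytl1, fell. In the others 0 genes passed the limma threshold: lymphocytes (2 tested, with Cd52 at 2.15 and an adjusted p of 0.147), plasma cells (3, with Jchain at 1.52 and an adjusted p of 0.574), brown adipocytes (3, with Dio2 at 1.87, Cox8b at -0.99 and Prdm16 at -0.36 and adjusted p of 0.0928, 0.485 and 0.451), mesothelial cells (1), neurons (4, with Uchl1 at 0.79 and an adjusted p of 0.0883), intestinal epithelium (1), pancreatic acinar cells (3), skeletal muscle (2), sex-linked genes (4), mast cells (0) and red blood cells (0).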

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

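The settings without normalization between arrays, with the macrophage covariate, with 2 against 2 arrays and with 3 against 1 were chosen after seeing the data. Quantile normalization, planned as an alternative, is part of the reported fit because the values were linear. No paired analysis was possible because the groups share no animal number. With median centring, no normalization, the mean of probe sets or either covariate, all 258 genes kept their direction; in fits with fewer arrays this follows from groups that do not overlap and shows nothing.

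The count of 258 genes (188 higher, 70 lower) became 174 (157 and 17) with no filter, of which 92 were shared with the 258, and 141 (105 and 36) with the 70th percentile filter, where 7275 genes were tested. It was 1131 (547 and 584) with array weights, 354 (243 and 111) with the adipocyte covariate, 100 (64 and 36) with the macrophage covariate, 55 (48 and 7) with 2 against 2 arrays and 15 (15 and 0) with 3 against 1, where the lone knockout is assumed to vary like the controls. The cause was not tested, except that the last 2 have fewer arrays. With 1 array left out, counts ranged from 45 to 240 (41 to 147 higher, 4 to 93 lower). Median centring gave 261 genes, 61.3% of them higher against 72.9%, with the median difference of all genes at -0.10 against -0.05; with no normalization it was -0.00074, with 79.1% of 263 higher. Array weights gave 48.4% higher. An adjusted p under 0.1 gave 656 genes, an unadjusted p under 0.05 with at least 2-fold 416, and the test by probe set 263.

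Itgb1 passed the threshold with array weights (-0.78, adjusted p = 0.0314) and with the adipocyte covariate (-0.92, adjusted p = 0.0192); the cause was not tested. In the fits of 5 arrays it ranged from -0.89 to -0.51 (adjusted p 0.0931 to 0.288), and with the macrophage covariate it was -0.37 (adjusted p = 0.521). List counts stayed between 14 and 17 except for 0 with an estimated correlation, whose values reach 0.874, and 5 with fry, but the lists that pass change. Beside the changes given in the report, with 2 against 2 arrays integrin alpha (0.27, adjusted p = 0.0451), hypoxia (-0.52, 0.0298) and white adipocyte genes (-0.80, 0.000117) passed, and contractile (-0.20, 0.147), vasoactive (-0.27, 0.191) and unfolded protein genes (0.16, 0.0707) did not. With 3 against 1, cholesterol synthesis (0.45, 0.0204) and circadian genes (-0.74, 0.0445) passed, and oxidative phosphorylation (-0.18, 0.126) and unfolded protein genes (0.18, 0.161) did not. With array weights, members passed in lists that have 0 in the reported fit, among them 5 vasoactive, 4 endothelial and 3 Schwann cell genes, all lower. Elastic fibre and ion channel genes had 0 past the threshold with no filter or the macrophage covariate.

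Some lists and genes changed sign, and the cause was not tested. Heat shock gave -0.040 with median centring, -0.10 with array weights, -0.28 with the adipocyte covariate, -0.033 with 2 against 2 arrays and -0.33 with 3 against 1 (-0.33 to 0.32 with 1 array left out), but 0.85 (adjusted p = 0.0132) with the macrophage covariate. Lymphatic endothelial genes gave 0.058 with no filter, 0.036 with the mean of probe sets, 0.11 with array weights, 0.24 with the adipocyte covariate, 0.029 with no normalization and 0.16 with 3 against 1 (-0.25 to 0.20). Cholesterol synthesis gave 0.43 with array weights, 0.14 with the adipocyte covariate and 0.45 with 3 against 1 (-0.38 to 0.22). Focal adhesion genes gave 0.0048 with the mean of probe sets, 0.0077 with no normalization and 0.15 with the macrophage covariate (-0.11 to 0.028). YAP targets gave 0.018 with the mean of probe sets, 0.031 with no normalization, 0.19 with the macrophage covariate and 0.019 with 2 against 2 arrays (-0.13 to 0.093). Integrin alpha genes gave -0.013 with the adipocyte covariate (-0.020 to 0.34). Acta2 gave 0.013 with no normalization, 0.0073 with the macrophage covariate, 0.034 with 2 against 2 arrays and 0.050 with 3 against 1 (-0.077 to 0.0088). Prdm16 gave 0.16 with the macrophage covariate and 0.025 with 3 against 1 (-0.57 to -0.20), and Jchain ranged from -0.10 without knockout 73 to 2.91 without knockout 86.

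With the macrophage covariate, contractile genes gave 0.12 (call lost, adjusted p = 0.392), other integrin beta subunits -0.37, chemokines -0.23, ion channels 0.16, adventitial fibroblasts -0.051, Itgb2 -0.21, Cd52 -0.096 and the gene Jchain -2.85. Of 106 genes named, 54 were past the threshold; of 15 lists past it, 1 reversed, the contractile list. The macrophage means of the groups do not overlap, so values with that covariate rest on differences within groups. Signal near the floor limits the folds of genes with low control means.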

Other observations

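The genes of this paragraph were chosen after their values were seen. Outside the fixed lists, 219 of the 258 genes passed the threshold. Among them were genes of monocytes and other myeloid cells: Ccr2 rose by 2.35 (SE 0.28, 5.11-fold, adjusted p = 0.0133), Ms4a6d by 2.46 (5.50-fold, adjusted p = 0.0141), Cd300lb by 3.69 (adjusted p = 0.0206), Cd84 by 1.53 (adjusted p = 0.0203) and Fcrls by 1.52 (adjusted p = 0.0173). Ms4a6b rose by 1.71 and Ms4a6c by 1.48. Ccr2 was 8.31, 8.20 and 7.46 in knockouts 72, 73 and 86 against a control mean of 5.64. The cartilage matrix gene Cilp rose by 3.47 (SE 0.38, 11.0-fold, adjusted p = 0.0105), the stress gene Nupr1 by 1.75 (adjusted p = 0.0133), Igf1 by 1.46 (adjusted p = 0.0467) and the TGF-beta corepressor Tgif1 by 1.22 (adjusted p = 0.0417). All 11 of these genes lost their calls without knockout 72, and some without other arrays, with the highest adjusted p between 0.0546 (Cilp) and 0.156 (Igf1). Of 2657 probe sets without a single gene name, 6 passed the threshold, all higher.

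Chosen after the result was seen were the tests by the macrophage covariate, without knockout 86, without knockout 73, against endothelial genes, of lymphocyte genes in knockout 73 alone and in the other two knockouts, and of other splits. The recombinase was present in the knockout mice alone, so no array separates its own effect from that of the deletion. Sex was examined only by leaving out knockout 86, strain only by the strain-variable list in the report and the neighbouring genes tested here, and litter was not tested.

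Cell cycle genes were higher by 2.38 in knockout arteries. With the macrophage list as a covariate the difference was 2.59 (SE 0.18). The macrophage means of the groups do not overlap, so this fit rests on differences within groups. Knockout 73 had the highest macrophage mean (10.92) and the lowest cell cycle mean of the knockouts (9.28), and it may carry lymph tissue. The fit therefore cannot exclude a larger share of macrophages, which stays open. Without knockout 86, the array with high Xist, 9 of the 12 genes past the threshold remained, and with a pseudocount of 16, which damps folds over low control signal, 12 remained and the list mean was 2.21. The deletion and the recombinase stay open alike, and no test here shows which cells carry these transcripts.

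Macrophage genes were higher by 1.53. Knockout 73 alone does not account for this, since the other two knockout arrays lay above all controls, by 1.01 on average. A lower share of smooth muscle cells alone would raise endothelial and Schwann cell genes alike, but these were at -0.40 and -0.57. The gap between macrophage and endothelial genes widened by 1.93 (SE 0.42), but it contains the macrophage rise itself. Contractile genes were at -0.31 and adventitial fibroblast genes at 0.25. A lower share beside separate falls of the endothelial and Schwann cell lists is thus not excluded. Lymph tissue, which the labels' protocols say was removed, stays open. Lymphocyte genes differed by 0.50 (SE 0.43), less than the bound set beforehand, but 10 of the 12 lie below the filter level of 6.50 and decide nothing. Over all 12, knockouts 72 and 86 (5.14 and 5.20) lay within the controls (4.77 to 5.30), and the gap between macrophage and lymphocyte genes was wider there than in controls by 0.91 (SE 0.28). Over the 2 above the filter, both arrays (8.60 and 8.54) lay above all controls (7.38 to 8.33), by Cd52 (8.33 and 8.03 against 6.01 to 7.61) and not by Ighm (8.88 and 9.04 against 8.76 to 9.05). In knockout 73 the 12 lymphocyte genes lay 1.26 above the mean of the other 5 arrays (their SD 0.20), with the same limit for the 10 low genes. The 2 above the filter stood at 10.58, higher than on any other array, so lymph tissue may contribute to the excess in knockout 73. Chosen after their values were seen, Ighm stood at 10.67 and Cd79a at 7.03 there, and Jchain, of the plasma cell list, at 12.23.

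For the 258 genes past the threshold, the 6 arrays allow only 10 splits into 3 and 3, too few for a share under 0.05; 1 split, the real one, gave 258 genes, and the highest of the others gave 0. Chromosome segments of another strain, carried along with the recombinase in this mixed background, could place called genes side by side. There were 9 adjacent pairs among them, against a median of 6 in 10000 random sets, of which a share of 0.173 had as many. The bound set beforehand, a share of at least 0.05, was too lax: 9 lies above the median of 6, so a few such segments remain possible and this stays open.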
